A study of Mus musculus with 6 samples.

How the data were processed

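Poly(A) RNA of 6 mouse embryonic hearts was sequenced from stranded libraries, 3 littermate controls and 3 cardiomyocyte-specific double knockouts of Rbpms and Rbpms2, per the labels. Groups and replicate numbers were taken from the sample titles and genotypes. Each sample is labelled as its own heart. Per the submitters' processing notes, Trimmomatic, STAR 2.4.2a and featureCounts 1.5.0 were used, with genome build mm10, and the notes also name DESeq and DESeq2; the role of each is not given in the sources used here, nor whether counting used strand. The deposited values are best described as a score: whole numbers of reads per gene that the authors had divided by a factor per sample and rounded, which is read from the values themselves, since the file headers state no unit.

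The factor was found by fitting the step between the values up to 150 in each sample. The step, which is what 1 read is worth, was 1.0194, 0.8595 and 1.4227 in control replicates 1 to 3 and 0.6921, 1.2102 and 0.9388 in knockout replicates 1 to 3. On simulated reads with known steps the largest error was 0.0009. Dividing each total by its step gave estimated depths of 12960709 to 25837261 reads. Where the step is below 1, different read numbers round to the same value, so exact reads cannot be recovered. The shallowest library, control replicate 3, has the coarsest values for low genes. Values at the low end carry counting error that the deposited scale does not show.

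The test planned before the data were examined was a negative binomial test on counts. Because the file turned out to hold another unit than that plan assumed, edgeR and DESeq2 were not run on these values, and the test named in the plan for normalized values was used: limma 3.58.1 in R 4.3.3, with a trend of variance on abundance, on log2(value + 1), for genes with a mean value of at least 10. A fold change is therefore on the log2(value + 1) scale and understates the change of low genes. P-values were adjusted by the Benjamini-Hochberg method over 15556 genes, with a threshold of 0.05. The design held the group only. On simulated data with the means and steps of these 6 samples and 200 changed genes, limma recovered 86.9% of changes of 2-fold and 58.6% of changes of 1.5-fold in the comparison of knockouts with controls, with 3 false calls. The spread between simulated samples was assumed, not estimated from these hearts, and genes varied independently. The rates therefore need not hold for the real data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

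A total of 38 gene lists were fixed before the data were examined, covering the heart's muscle, cell cycle, metabolism, stress and signalling genes and markers of other cell types. Symbols were matched exactly, and 29 of 1064 list symbols were unmatched; 14 gene names in the table had been turned into dates, such as those of septins. Lists with at least 5 tested members, 36 in all, were tested with camera with a correlation between genes preset at 0.01, adjusted over the lists; 23 passed, 15 up and 8 down. With an estimated correlation 0 passed (lowest adjusted p = 0.22; 6 at an unadjusted p under 0.05), and 11 passed with fry, which asks whether the members of a list move on balance one way. For epicardial markers the estimated correlation was 0.01, the same as the preset one, yet the camera adjusted p went from 0.000105 to 0.22. The loss of calls is therefore not a measure of correlation between genes alone. With the preset correlation, splits of the hearts other than the real one also passed 8 to 20 lists. A pass there is therefore not by itself a sign of the knockout. Because these versions disagree, member counts are given first for each list.

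The genes named were set by a rule fixed beforehand: Rbpms and Rbpms2; the 10 largest rises and 10 largest falls among genes past the threshold, in the upper part of the tested genes by mean value (at or above the median of 409.7), with groups that do not overlap, leaving out predicted genes, pseudogenes and sex markers; and for each list up to 4 members past the threshold with the smallest p or, where none passed, up to 2 given as values. Some genes that this rule takes are not reported here. Of 45706 gene identifiers, 45143 were found in the GENCODE M21 annotation of the same build, which gave the coordinates. All 37 mitochondrial genes are listed at 0 in every sample and were left out.

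Alternatives planned beforehand were limma-voom on estimated reads, pseudocounts of 0.1 and 10, no filter and a stricter filter (at least 50 in each of 3 samples), the replicate number as a block, a test against a fold change of 1.2, leaving out each heart, and for lists an estimated correlation and fry. Quantile normalization, equal totals and embryo sex as a term were added after the data were seen. Replicates of 1 group differed by more than sampling noise in every pair, so that no library was counted as a repeat of another.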

Results

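The series profiled poly(A) RNA of mouse embryonic hearts by stranded, paired-end RNA sequencing. Per the labels, 3 hearts were littermate controls with loxP-flanked (floxed) alleles of Rbpms and Rbpms2, and 3 were double knockouts that carried the same alleles and a Cre recombinase driven by the alpha-myosin heavy chain promoter, which is active in cardiomyocytes. RBPMS and RBPMS2 are RNA-binding proteins with an RNA recognition motif. The deposited table gave 45706 genes as read numbers already divided by a factor per sample and rounded, so that the totals were close to equal, from 17861435 to 18439201 per heart. The spacing of the low values gave an estimated depth before that division of 17680629, 21331727 and 12960709 reads for control replicates 1, 2 and 3, and of 25837261, 14759077 and 19064889 for knockout replicates 1, 2 and 3. The labels do not give the embryonic day. The genotype labels name Cre in all 3 knockouts and in no control, so the comparison covers the transgene together with the deletion.

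The comparison asked how loss of both proteins from cardiomyocytes changed the transcripts of the embryonic heart. The targeted genes were examined first. Rbpms (ENSMUSG00000031586; mm10 chromosome 8, 33782643 to 33929863, minus strand) was at 6998, 3868 and 7656 in control replicates 1 to 3 and at 1134, 1117 and 852 in the knockouts, a mean of 6170 ± 2020 against 1030 ± 158 (SD, n = 3 each). Its log2 fold change was -2.53 (SE 0.22, limma adjusted p = 0.000325). Rbpms2 (ENSMUSG00000032387; chromosome 9, 65629648 to 65660528, plus strand) was at 1711, 1362 and 1998 in the controls and at 879, 1003 and 911 in the knockouts, a mean of 1690 ± 319 against 931 ± 64.4 (SD, n = 3 each). It fell by 0.84 on the log2 scale (SE 0.12, limma adjusted p = 0.00207). Control replicate 2 held the lowest value of the 3 controls for both genes and still lay above every knockout. The values cover whole genes, so reads from cells without Cre and from exons outside the deleted part are included.

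**Figure D1:**
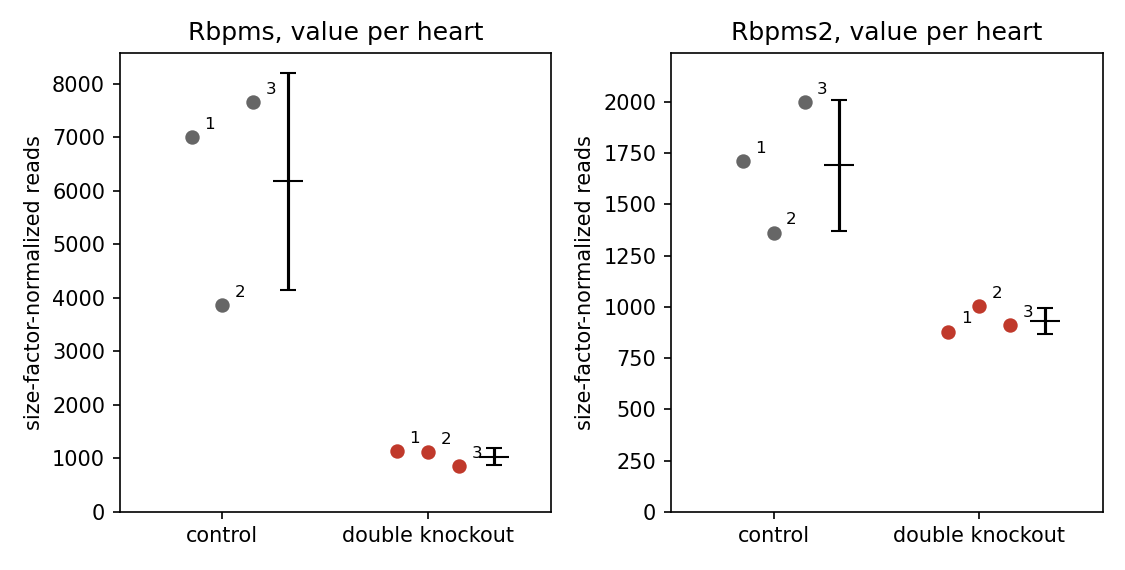
Normalised read numbers of Rbpms and Rbpms2 (vertical axes, starting at 0) in the 3 control and 3 knockout hearts; points are single hearts with their replicate number, and the bar beside each group is the mean ± SD. All 3 knockouts lie below all 3 controls for both genes, and control replicate 2 is the lowest control, at 3868 for Rbpms and 1362 for Rbpms2.

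Among genes with a mean value of at least 409.7, the median of the genes tested, the 10 largest falls included Acta1, Cnn1, Acta2, Myl9 and Myh6, and the 10 largest rises included Sdc4, the natriuretic peptide gene Nppa, Etv5 and Itgav. Of 15556 genes tested, 2670 passed an adjusted p of 0.05 in limma, 1339 higher and 1331 lower in the knockouts, and 333 of them changed by at least 1 on the log2 scale, 239 up and 94 down. The 2 groups did not overlap in 2650 of the 2670 genes. Over all genes tested they did not overlap in 35.4%, where chance gives 10%. The even balance depended on the scaling: with values scaled to equal totals, 1569 genes were higher and 1091 lower. The number of genes depended on single hearts: without each heart in turn it ranged from 1305 to 2370. Against a fold change of 1.2 in place of 0, 418 genes passed, and with no filter on low values 1755 did.

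Among genes above that mean value, Acta1, the skeletal muscle alpha-actin, had the largest fall, from 2060 ± 126 to 354 ± 167 (SD, n = 3 each), a log2 fold change of -2.64 (SE 0.25, limma adjusted p = 0.000351). Cnn1, which encodes the smooth muscle protein calponin, changed by -2.16 (SE 0.24) and Acta2, the smooth muscle alpha-actin, by -1.74 (SE 0.13). Myh6, the alpha-myosin heavy chain of heart muscle, was among the most abundant transcripts and changed by -1.53 (SE 0.11), from 98500 ± 10600 to 34200 ± 4610 (SD, n = 3 each). Ppp1r1b, a phosphatase inhibitor, changed by -1.58 (SE 0.12). Crhr2, a receptor for the urocortin peptides, changed by -1.41 (SE 0.10), Myl9, a regulatory myosin light chain of smooth muscle, by -1.35 (SE 0.14), and Abcc8, the sulfonylurea receptor subunit of potassium channels, by -1.29 (SE 0.11). Eno1b, a close copy of the glycolytic gene Eno1, changed by -1.49 (SE 0.30). Rbpms completes the 10 largest falls above that mean value. Reads can be shared between Eno1b and Eno1, between the actin genes and between Myh6 and its neighbour Myh7, so those values are less certain.

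Among genes with a mean value of at least 409.7, the largest rise was in Sdc4, a heparan sulfate proteoglycan of the cell surface, from 354 ± 31.8 to 1350 ± 306 (SD, n = 3 each), a log2 fold change of 1.90 (SE 0.15, limma adjusted p = 0.00024). Nppa rose from 4610 ± 1590 to 16200 ± 2380 (SD, n = 3 each), by 1.85 (SE 0.20, limma adjusted p = 0.000626). Etv5, an ETS transcription factor, rose by 1.72 (SE 0.14), and Itgav, the integrin alpha-V subunit, by 1.65 (SE 0.11). The semaphorin gene Sema3b rose by 1.45 (SE 0.13), the adhesion receptor gene Adgrg6 by 1.37 (SE 0.11) and Cdkn1a, the cyclin-dependent kinase inhibitor p21, by 1.32 (SE 0.11). Slit2, a secreted guidance ligand, rose by 1.31 (SE 0.14), Angpt1, a ligand of the receptor Tie2, by 1.31 (SE 0.12), and Clu, the chaperone clusterin, by 1.29 (SE 0.13). All 20 of these genes passed the threshold under each alternative tried, including without each heart in turn.

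**Figure D2:**
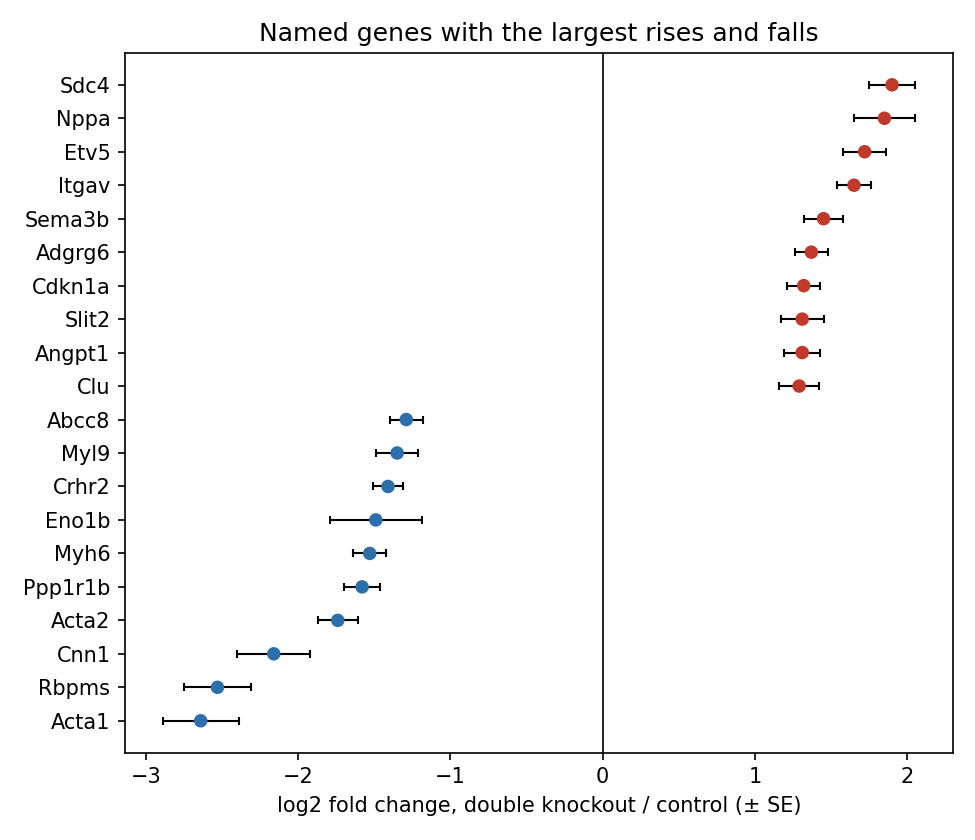
Log2 fold changes, double knockout over control (horizontal axis), of the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold with a mean value of at least 409.7; points are limma estimates over 3 hearts per group and bars are standard errors. Acta1 at -2.64 and Sdc4 at 1.90 are the ends of the range.

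Genes of the cell cycle fell together. Of 34 measured genes of mitosis, 33 fell, and 32 to 33 without each heart in turn. Adjusted over the list alone, 33 fell and 1 rose. Bub1 and Bub1b, kinases of the spindle checkpoint, each fell by 0.85 on the log2 scale (SE 0.08 each), Ccnb2, a mitotic cyclin, by 0.74 (SE 0.07) and Ckap2l by 0.76 (SE 0.08). Of 36 genes of DNA replication, 28 fell and 0 rose, and 32 fell adjusted over the list alone. They included Ccna2, a cyclin of S phase, which fell by 0.93 (SE 0.07), and both subunit genes of ribonucleotide reductase, Rrm1 by 0.61 (SE 0.07) and Rrm2 by 0.65 (SE 0.07), and Mcm7 of the replicative helicase by 0.63 (SE 0.07). Of 23 genes of cytokinesis, 14 fell and 0 rose. Adjusted over the list alone, 14 fell and 1 rose. Among them Prc1 fell by 0.85 (SE 0.07), Kif20a by 0.85 (SE 0.09), Iqgap3 by 0.78 (SE 0.07) and Racgap1 by 0.71 (SE 0.07). In camera with a preset correlation these lists had adjusted p = 9.08e-28 for mitosis, 3.01e-19 for replication and 3.88e-08 for cytokinesis. The adjusted p was 0.22, 0.25 and 0.22 with an estimated correlation. In the same hearts markers of endothelial cells, epicardial cells, fibroblasts and macrophages were higher, by median log2 changes of 0.23, 0.35, 0.39 and 0.76.

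Cell cycle inhibitors and p53 targets moved in both directions, 9 of 28 up and 2 down, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.000433; adjusted p = 0.22 with an estimated correlation). Beside Cdkn1a, the stress gene Ddit4 rose by 0.62 (SE 0.09), whereas the 2 that fell, Cdkn2c by 0.69 (SE 0.08) and Ckap2 by 0.60 (SE 0.08), are an inhibitor of the cyclin D kinases and a spindle protein.

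Contractile genes changed unevenly. Of 40 sarcomere genes, 10 fell and 5 rose, or 12 and 7 adjusted over the list alone, with a median log2 change of -0.14 (camera adjusted p = 0.0499; adjusted p = 0.61 with an estimated correlation). Without each heart in turn, 3 to 11 sarcomere genes fell and 2 to 6 rose. With quantile normalization the median was -0.01, and 8 fell and 7 rose. Apart from Myh6 and Acta1, the atrial light chain gene Myl4 fell by 0.65 (SE 0.10), and Myom2, a protein of the sarcomere M-band, rose by 1.05 (SE 0.12). Of 20 smooth muscle contractile genes 7 fell and 0 rose, the same number adjusted over the list alone (camera adjusted p = 0.0039; adjusted p = 0.25 with an estimated correlation). Beside Acta2, Cnn1 and Myl9, Cnn2 fell by 0.39 (SE 0.07). Of 31 genes of calcium handling and ion channels, 7 fell and 5 rose, or 9 and 10 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.308). Without each heart in turn 0 to 4 rose. Kcnd2, a potassium channel subunit, fell by 1.74 (SE 0.21), Atp2a2, the calcium pump of the sarcoplasmic reticulum, by 0.66 (SE 0.08), Kcnj5 by 0.65 (SE 0.11) and Jph2, a junctophilin, by 0.52 (SE 0.09). Of 29 intercalated disc and adhesion genes, 5 fell and 5 rose, or 5 and 6 adjusted over the list alone (camera adjusted p = 0.867), with Pkp4 falling by 0.60 (SE 0.06), Tln2 by 0.56 (SE 0.06) and Ctnna1 by 0.38 (SE 0.08). Without each heart in turn 4 to 5 of this list fell and 2 to 5 rose.

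Fetal and stress response genes rose in 8 of 19 cases and fell in 2, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.00436; adjusted p = 0.48 with an estimated correlation), and 4 to 7 rose without each heart in turn. Nppb, the B-type natriuretic peptide gene, rose by 0.57 (SE 0.10), and Fhl2 fell by 0.42 (SE 0.08). Of 11 genes of the trabecular myocardium, the inner layer of the ventricle wall, 7 rose and 1 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.00218; adjusted p = 0.39 with an estimated correlation). They included Nppa and Slit2 and the homeobox genes Irx5, up by 1.28 (SE 0.19), and Irx3, up by 1.11 (SE 0.17). Of 9 compact myocardium genes 2 rose and 2 fell, or 2 and 3 adjusted over the list alone (camera adjusted p = 0.867): Ccnd2 rose by 0.39 (SE 0.07) and Fgfr2 by 0.54 (SE 0.11), and Mycn fell by 0.55 (SE 0.09) and Hey2 by 0.42 (SE 0.10). Of 18 atrial genes 5 rose and 3 fell, or 6 and 3 adjusted over the list alone (camera adjusted p = 0.257). Of 12 ventricular genes 3 rose and 2 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.763), among them Lbh, which fell by 0.47 (SE 0.07), and Pln, which rose by 0.28 (SE 0.08). Without each heart in turn 0 to 2 rose. Of 30 cardiac transcription factors 5 rose and 4 fell, or 5 and 5 adjusted over the list alone (camera adjusted p = 0.285), and 5 to 6 rose and 2 to 7 fell without each heart in turn. Srf, the serum response factor, fell by 0.63 (SE 0.08), and Foxc1 rose by 0.88 (SE 0.13).

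**Figure D3:**
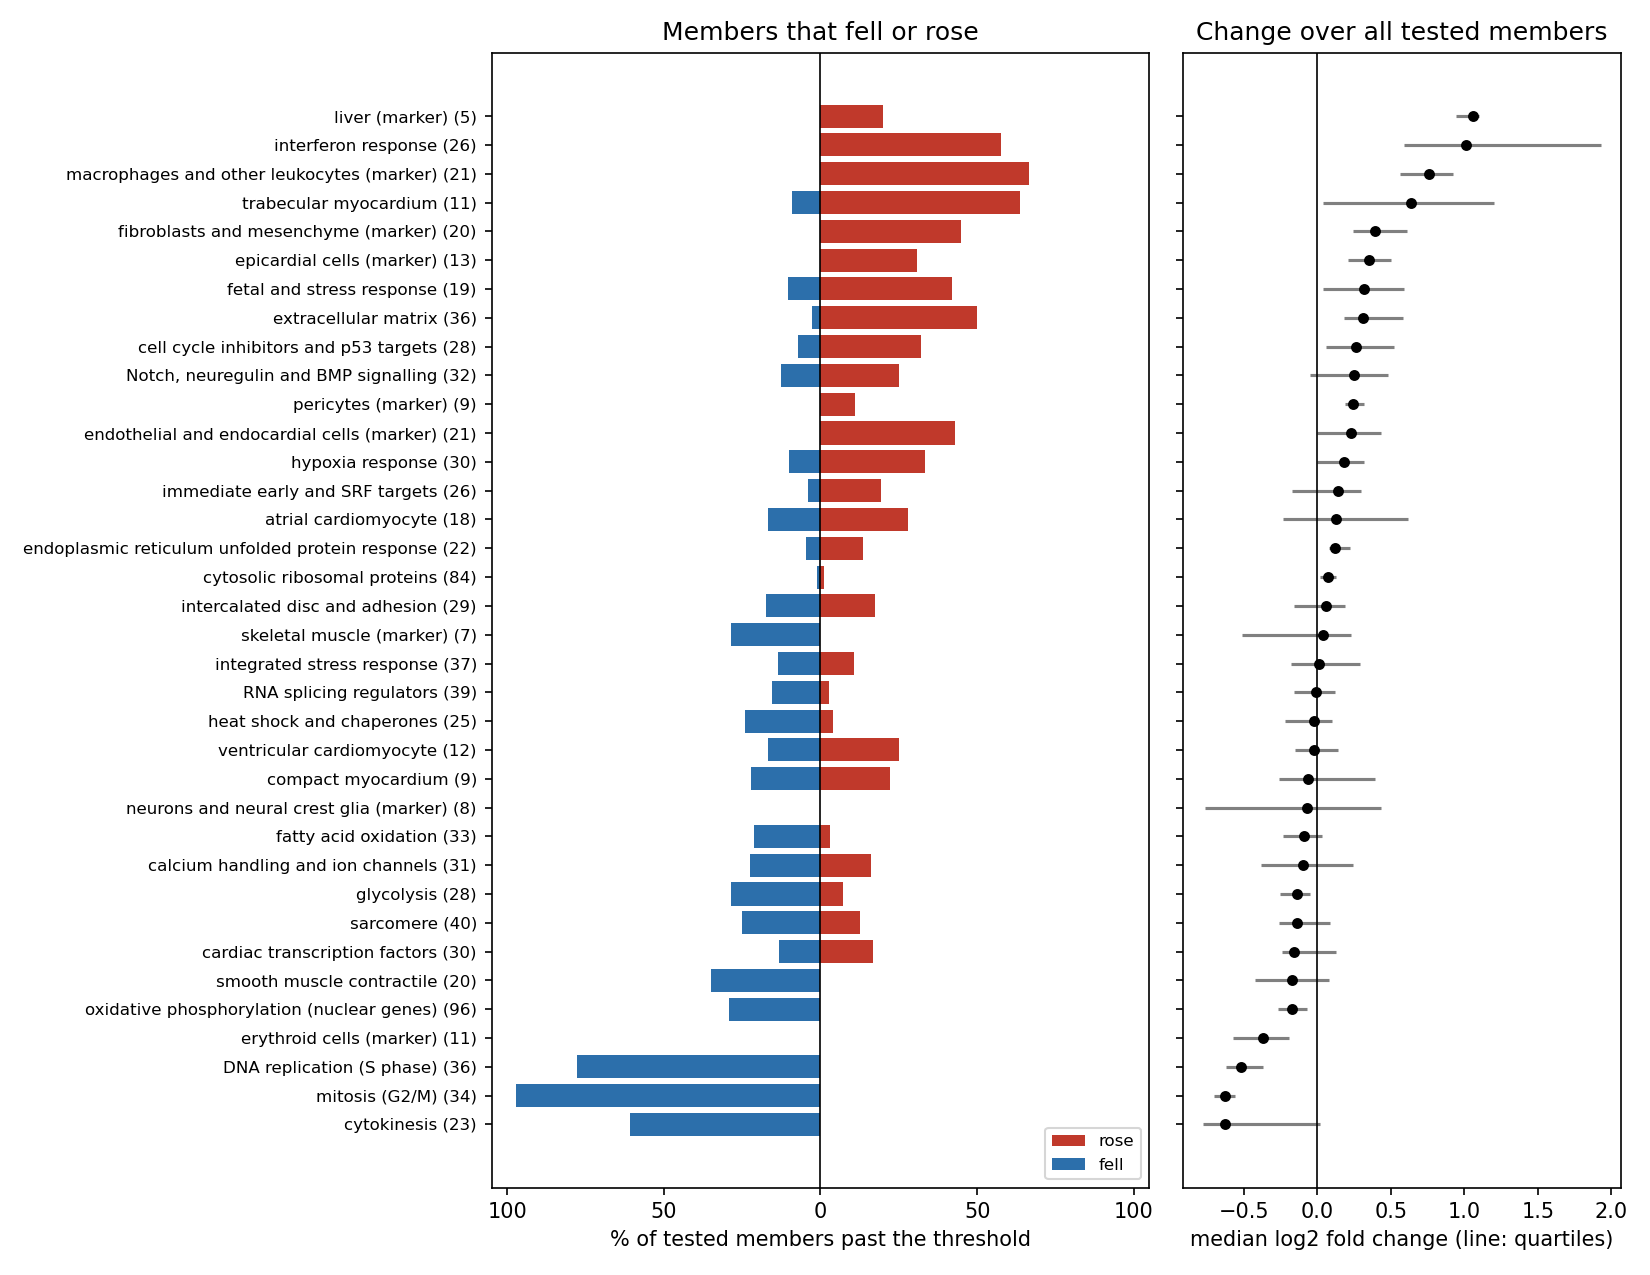
The left panel gives, for each of the 36 tested gene lists (number of tested members in brackets), the percentage of members that rose (red) or fell (blue) past an adjusted p of 0.05 over all genes; the right panel gives the median log2 fold change (points) and the quartiles (lines) over all tested members. Mitosis genes fell in 33 of 34 cases, and 14 of 21 macrophage and leukocyte markers rose.

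Of 96 nuclear genes of oxidative phosphorylation, 28 fell and 0 rose, or 40 and 1 adjusted over the list alone, with a median log2 change of -0.17 (camera adjusted p = 5.73e-09; adjusted p = 0.48 with an estimated correlation). The count of 28 was 7 to 34 without each heart in turn, 17 with equal totals and 15 with sex as a term. Markers of endothelial cells, epicardial cells, fibroblasts and macrophages were higher in the same hearts, by median log2 changes of 0.23, 0.35, 0.39 and 0.76. Cyc1 fell by 0.44 (SE 0.08), Sdha by 0.41 (SE 0.08), Sdhb by 0.37 (SE 0.07) and Uqcrfs1 by 0.36 (SE 0.07). The 13 mitochondrial genes of the same complexes are listed at 0 in all 6 hearts and were not tested. Of 33 genes of fatty acid oxidation 7 fell and 1 rose, the same numbers adjusted over the list alone (camera adjusted p = 0.035; adjusted p = 0.49 with an estimated correlation), and 4 to 8 fell without each heart in turn. Ppargc1b, a coactivator of mitochondrial genes, fell by 0.78 (SE 0.10), Cpt2 by 0.44 (SE 0.08) and Echs1 by 0.38 (SE 0.06), while Lpl, lipoprotein lipase, rose by 0.53 (SE 0.09). Of 28 glycolysis genes 8 fell and 2 rose, or 10 and 2 adjusted over the list alone (camera adjusted p = 0.00436; adjusted p = 0.53 with an estimated correlation), and 3 to 7 fell without each heart in turn; Pfkl fell by 0.58 (SE 0.10), the glucose transporter gene Slc2a1 by 0.45 (SE 0.08) and Hk2 by 0.34 (SE 0.07), and Pfkfb2 rose by 0.54 (SE 0.09). Of 30 hypoxia response genes 10 rose and 3 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.0149; adjusted p = 0.49 with an estimated correlation), and 4 to 10 rose without each heart in turn. Hmox1, heme oxygenase, rose by 0.99 (SE 0.17), and Pdk1 fell by 0.50 (SE 0.07).

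In the unfolded protein response of the endoplasmic reticulum 3 of 22 genes rose and 1 fell, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.00365; adjusted p = 0.25 with an estimated correlation), and 1 to 4 rose and 0 to 1 fell without each heart in turn. Atf6 rose by 0.41 (SE 0.07), Dnajb11 by 0.25 (SE 0.06) and Pdia3 by 0.23 (SE 0.06), and Ero1lb fell by 0.66 (SE 0.19). In the integrated stress response 4 of 37 rose and 5 fell, or 4 and 7 adjusted over the list alone (camera adjusted p = 0.867). Slc7a1, an amino acid transporter gene, rose by 0.61 (SE 0.08) and Trib3 rose from 37, 52 and 46 in the controls to 84, 86 and 101 in the knockouts, and Gars, a tRNA synthetase gene, fell by 0.61 (SE 0.08). Of 25 heat shock and chaperone genes 1 rose and 6 fell, or 1 and 7 adjusted over the list alone (camera adjusted p = 0.183). Stip1 fell by 0.38 (SE 0.06), Hspa4l by 0.44 (SE 0.09), and 2 to 5 fell without each heart in turn. Of 84 cytosolic ribosomal protein genes 1 rose and 1 fell, with Rpl39 rising by 0.29 (SE 0.07), and none passed adjusted over the list alone, against 13 higher and 1 lower at an unadjusted p under 0.05; the median was 0.07 (camera adjusted p = 0.00631; adjusted p = 0.61 with an estimated correlation). With equal totals 6 ribosomal protein genes rose and 1 fell, with quantile normalization 5 and 1, and with the replicate block 6 and 1. Of 39 splicing regulators 6 fell and 1 rose, the same numbers adjusted over the list alone (camera adjusted p = 0.269), and 1 to 5 fell without each heart in turn. Rbm24, a muscle RNA-binding protein, fell by 0.41 (SE 0.06), Celf1 by 0.27 (SE 0.07) and Mbnl3 by 0.69 (SE 0.19), and Mbnl1 rose by 0.49 (SE 0.12).

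Extracellular matrix genes rose in 18 of 36 cases and fell in 1, or 20 and 1 adjusted over the list alone (camera adjusted p = 3.4e-09; adjusted p = 0.25 with an estimated correlation). The proteoglycan gene Vcan rose by 0.94 (SE 0.09), Tnc by 0.79 (SE 0.11), Fbn1 by 0.65 (SE 0.08) and Col6a3 by 0.60 (SE 0.07), and fibroblast markers were higher in the same hearts, by a median log2 change of 0.39. The fibroblast list shares Col1a1, Col1a2, Col3a1, Postn and Vcan with the matrix list. Of 32 genes of Notch, neuregulin and BMP signalling 8 rose and 4 fell, or 12 and 4 adjusted over the list alone (camera adjusted p = 0.00365; adjusted p = 0.48 with an estimated correlation), and 5 to 14 rose without each heart in turn. Endothelial and endocardial markers were higher in the same hearts: 9 of 21 rose, with a median log2 change of 0.23. Nrg1, a growth factor for cardiomyocytes, was low in every heart, at 5, 12 and 7 in the controls and 35, 45 and 48 in the knockouts, and rose by 2.34 (SE 0.33). Id2 rose by 0.87 (SE 0.10), Id3 by 0.63 (SE 0.12) and Hey1 by 0.62 (SE 0.11). Of 26 immediate early genes and targets of the serum response factor 5 rose and 1 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.254): Fos rose by 1.15 (SE 0.23), Actg1 by 0.62 (SE 0.10) and Btg2 by 0.51 (SE 0.10). The 1 that fell was Srf itself, by 0.63 (SE 0.08). Acta1, Acta2, Cnn1 and Myl9, which fell, are not in this list, so its counts do not cover those contractile genes.

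Interferon-responsive genes rose in 15 of 26 cases and fell in 0, or 20 and 0 adjusted over the list alone (camera adjusted p = 6.59e-09; adjusted p = 0.48 with an estimated correlation), and 8 to 19 rose without each heart in turn. With limma-voom 9 rose, and with no filter on low values 7 did. Xaf1 was at 54, 57 and 68 in the controls and at 154, 535 and 295 in knockout replicates 1 to 3, and Irf7 at 28, 29 and 36 and at 69, 280 and 157. Ifi27 rose by 0.95 (SE 0.14) and B2m, the light chain of class I antigen-presenting molecules, by 0.57 (SE 0.09). Macrophage and leukocyte markers were higher in the same hearts, by a median log2 change of 0.76.

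Some markers of macrophages, endothelial cells, fibroblasts, epicardial cells and pericytes rose in the knockouts, and none of these lists had a member that fell past the threshold over all genes. Of 21 macrophage and leukocyte markers 14 rose and 0 fell, or 19 and 0 adjusted over the list alone (camera adjusted p = 3.87e-10; adjusted p = 0.25 with an estimated correlation), and 9 to 15 rose without each heart in turn. Fcer1g rose by 1.08 (SE 0.17), C1qa by 0.95 (SE 0.17), Cx3cr1 by 0.90 (SE 0.15) and Csf1r by 0.82 (SE 0.13). Of 21 endothelial and endocardial markers 9 rose and 0 fell, or 12 and 0 adjusted over the list alone (camera adjusted p = 2.62e-05; adjusted p = 0.25 with an estimated correlation), with Npr3 up by 0.95 (SE 0.07), Emcn by 0.91 (SE 0.06), Plvap by 0.89 (SE 0.13) and Ramp2 by 0.45 (SE 0.07). Of 20 fibroblast and mesenchyme markers 9 rose and 0 fell, or 13 and 0 adjusted over the list alone (camera adjusted p = 7.03e-08; adjusted p = 0.25 with an estimated correlation), among them Mfap4 by 0.92 (SE 0.13), Ogn by 0.87 (SE 0.14) and Prrx1 by 0.69 (SE 0.11). Of 13 epicardial markers 4 rose and 0 fell, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.000105; adjusted p = 0.22 with an estimated correlation): Bnc1 by 1.02 (SE 0.16), Tcf21 by 0.78 (SE 0.14), Sema3d by 0.66 (SE 0.08) and Lrrn4 by 0.50 (SE 0.14). Of 9 pericyte markers 1 rose, Mcam by 0.34 (SE 0.07), or 2 adjusted over the list alone (camera adjusted p = 0.0344; adjusted p = 0.42 with an estimated correlation).

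Of 11 erythroid markers 0 passed over all genes, and 1 was higher and 5 lower both adjusted over the list alone and at an unadjusted p under 0.05 in limma (camera adjusted p = 0.0859); Hba-a1 was at 7848, 8216 and 13295 in the controls and 6048, 5680 and 7708 in the knockouts, and reads can be shared with its twin copy. Hbb-y was at 114, 106 and 154 and at 196, 272 and 146. Of 8 neuronal and neural crest markers 0 passed, also adjusted over the list alone, against 1 higher and 2 lower at an unadjusted p under 0.05 in limma (camera adjusted p = 0.787). Dbh was at 33, 21 and 38 and at 19, 18 and 12, and Elavl4 at 27, 35 and 41 and at 24, 23 and 14. Of 7 skeletal muscle markers 2 fell, the same number adjusted over the list alone, Ckm by 0.61 (SE 0.09) and Tnni2 by 0.92 (SE 0.25). Ckm was abundant in the control hearts, at 28500 ± 3000 (SD, n = 3), so its fall need not come from skeletal muscle cells. The list's median of 0.04 and mean of -0.15 differed in sign, and its median was -0.07 with quantile normalization and -0.51 over the 4 members past the stricter filter (camera adjusted p = 0.3). Of 5 liver markers past the filter, 1 rose, Ahsg by 1.28 (SE 0.24), the same number adjusted over the list alone (camera adjusted p = 0.0499; adjusted p = 0.48 with an estimated correlation). The liver markers differed between hearts within each group: their mean score on the log2 scale, centred over the 6 hearts, was 0.18, -0.79 and -0.88 in control replicates 1 to 3 and 1.22, 1.18 and -0.91 in knockout replicates 1 to 3, a difference of 0.99 (SE 0.78). The lung epithelium list had no gene past the filter.

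Member counts were sensitive to single hearts: in 28 of 36 lists the number that rose or fell moved by over 1.5 times without at least 1 heart, in 21 of them without knockout replicate 2 and in 20 without control replicate 3. By the same measure 8 lists moved with equal totals and 5 with quantile normalization. The measure also counts a move from 0 to 1, as for cytokinesis genes that rose. Every fit without 1 heart called fewer genes (1305 to 2370) than the full fit (2670), so loss of sample size is not separated from the effect of single hearts. Of the named genes, 16 lost their call without at least 1 heart, among them Celf1, Dnajb11, Ero1lb, Fgfr2, Fkbp4, Hey2, Hspb8, Lrrn4, Mbnl1, Mbnl3, Mpped2, Pdia3, Pln, Rpl39 and Tnni2.

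Transcripts of Xist and of the Y chromosome showed 2 female hearts and 1 male heart among the controls, and 1 female and 2 male among the knockouts. All 2670 genes kept their direction within each sex, which follows for most of them from groups that do not overlap. With sex as a term in limma, chosen after the data were seen, 2090 genes passed, 1963 of them among the 2670.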

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

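The scalings and the sex term were chosen after the data were seen; the other alternatives were planned. Rbpms and Rbpms2 stayed lower and past the threshold under every alternative run, at -2.83 to -2.34 and -0.99 to -0.72 without each heart in turn, and all 20 genes with the largest changes above the median mean value passed each time. The planned edgeR and DESeq2 alternatives were not run because the values are not counts. The number of genes past the threshold, 2670, was 1755 with no filter on low values (846 higher), where 26986 genes share the adjustment, and 418 (211 higher, 207 lower) against a fold change of 1.2. Without each heart in turn it ranged from 1305 (without knockout replicate 2) to 2370, and was 1669 without control replicate 3, with 614 to 1237 higher and 691 to 1225 lower. Genes with a log2 change of at least 1, 333, numbered 188 with a pseudocount of 10, 172 with the stricter filter, which tests fewer genes, and 164 against a fold change of 1.2; a larger pseudocount shrinks the changes of low genes. Deviations of same-numbered hearts correlated at -0.11, -0.7 and 0.05, which gave no sign of a pairing by replicate number. Same-numbered hearts were always of opposite sex, however, and hearts of the same sex across the groups correlated at 0.33 to 0.49. The check therefore cannot exclude a pairing. The replicate block gave 3530 genes. The 23 lists past the threshold became 0 with an estimated correlation (6 at an unadjusted p under 0.05) and 11 with fry, which asks another question. The 0 does not come from correlation alone, since the estimate for epicardial markers was 0.01, as preset.

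Of 129 genes named in all, 71 kept direction and side of the threshold under every alternative, and none reversed. Of 36 lists 7 did, since none passed with an estimated correlation, and 5 changed the direction of the camera test, none of them past the threshold in the main test; the cause was not tested. Their mean log2 changes there were 0.03 with quantile normalization for the intercalated disc list, 0.00 with the replicate block and 0.01 with quantile normalization for compact myocardium, 0.03 with quantile normalization for ventricular genes, 0.10 with no filter and 0.03 with the stricter filter for the integrated stress response, and 0.18 with no filter for neuronal markers. Without each heart in turn they ranged from -0.01 to 0.05 for the intercalated disc list, -0.07 to 0.05 for compact myocardium, 0.02 to 0.16 for the integrated stress response and -0.13 to 0.16 for neuronal markers. Control replicate 3, the shallowest library, has the coarsest low values.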

Other observations

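All tests of explanations in this part, and the criteria for them, were chosen after the values were seen. Of the 10 splits of the 6 hearts into 3 and 3, the real one gave 2670 genes and the others 0 to 7. For gene lists the real one gave 23 and the others 8 to 20. Camera with the preset correlation thus passed many lists under other groupings too. In each case only 1 split, the real one, gave as large a result, and 10 splits are too few for a share under 0.05. Each other split sets 2 hearts of a genotype against 1 and so holds part of the genotype contrast.

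Control replicate 2 had low Rbpms and Rbpms2, lying 0.55 and 0.53 of the way from the mean of the other 2 controls to the knockout mean. Over the 1874 other genes called without it, its median place was 0.18 of the way (quartiles 0.02 and 0.36), against 0.11 for control replicate 1 and 0.00 for control replicate 3 placed in the same manner. Over the 125 of them with a log2 change of at least 1 and a mean value of at least 100, its median place was 0.17. Control replicates 1 and 3 lay at 0.01 and -0.01 over the 98 and 95 such genes called without each of them. The gap of 0.37 to its Rbpms level was only just above the interquartile range of 0.34, the bound set for this test. That argues only weakly against knockout RNA in the library, or a full knockout labelled as a control, as the whole cause. Either would move Rbpms and the other genes alike. A control label on a heart with a lower dose of the targeted genes is not covered. The bound is also not strict. Rbpms in control replicate 3 lay -0.51 from that heart's median, beyond its interquartile range of 0.41, though control replicate 2 was part of its reference. A large share of RNA from the sequenced knockouts is further argued against by genes that were low in control replicate 2. Xist was at 14, against 15586 in knockout replicate 2, and Rps3a3 at 20, against 1834 in knockout replicate 3. Gm11469 and Gm14267 were at 9 and 5, against 166 and 89 in knockout replicate 1. RNA of a heart outside the series is not covered. Control replicate 2 was the only male control and differed from the female controls in log2 Rbpms by -0.92, while male knockouts differed from the female knockout by -0.18. A criterion on the size of that gap alone would count against sex of the embryo, but knockouts have lost most of the transcript, so sex and other causes cannot be told apart. The 5 genes beside Rbpms that rose, named below and chosen because they rose, lay 0.33 to 0.67 of the way in this heart. A lower dose of the targeted genes or another local cause in this heart may be considered and was not tested.

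Higher markers of other cell types were found in the knockouts for macrophages, endothelial cells, fibroblasts and epicardial cells and for 1 pericyte and 1 liver marker, not for erythroid, neuronal or skeletal muscle markers, of which none rose past the threshold over all genes. The mean rise of macrophage markers exceeded that of endothelial markers by 0.49 (SE 0.10 over the hearts). For macrophage markers this argues against a lower share of cardiomyocytes as the whole cause, because that would raise both lists alike. Mean rises of endothelial, epicardial and fibroblast markers were closer, at 0.28, 0.41 and 0.44, and the comparison does not decide for them. Endothelial markers were uneven, with quartiles of 0.0 and 0.43, and the SE does not cover the choice of markers. A change in the number or state of macrophages may contribute and stays open.

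Interferon-responsive genes were highest in knockout replicate 2. A single knockout library is argued against, since 17 of 26 members lay above all 3 controls in both other knockouts. The members moved together (estimated correlation 0.698), so they are not separate evidence and the comparison rests on few hearts. The list's mean score was -0.06 and 0.53 in knockout replicates 1 and 3, 1.29 in knockout replicate 2, and -0.74, -0.51 and -0.5 in control replicates 1 to 3. More macrophages alone remain open: the mean rise of the interferon list exceeded that of the macrophage list by 0.40 (SE 0.32), too uncertain to decide, and the 2 cannot be told apart here. Between knockout replicates 2 and 1 the median log2 difference was 1.26 for the interferon list and 0.48 for macrophage markers, from 1 heart each.

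Within 1 Mb of the start of Rbpms, 5 of 14 genes with a mean value of at least 100 rose (35.7%) and 0 fell. A share as large was found around 1.3% of 14570 genes. Those that rose were Saraf by 0.63 (SE 0.10), Dctn6 by 0.60 (SE 0.13), Gtf2e2 by 0.50 (SE 0.10), Leprotl1 by 0.42 (SE 0.11) and Gsr by 0.38 (SE 0.08), genes chosen after their values were seen. Nrg1, on the same chromosome at 31814551 to 32884029, lay below that mean value and was not counted. Leaving out genes annotated to the X or Y chromosome, 12 genes that did not pass the threshold, 6 of them pseudogenes and 1 without an annotated position, had a gap of over 1.8 in log2(value + 8) between hearts next to each other in rank and a highest value of at least 80. Slc7a11, a cystine transporter gene, was at 167, 4 and 181 in the controls and 8, 150 and 177 in the knockouts, and Rps3a3 at 1629, 20 and 9 and at 19, 2039 and 1834.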
